A study of Rattus norvegicus with 6 samples.

How the data were processed

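Small RNA was sequenced from AR42J cells, an established rat cell line of the exocrine pancreas. Of the 6 libraries, 3 came from untreated cells and 3 from cells given 200 µM sodium taurocholate for 30 min. Groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

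Per the labels' protocols, total RNA was deacylated, cyclic phosphates were removed from 3′ ends, 5′ hydroxyls were phosphorylated and methyl groups that block reverse transcription were removed, and libraries were cut by size from a gel. Reads were single-end on an Illumina NextSeq. Per the submitters' processing notes, the tools were FastQC, cutadapt and Novoalign 2.07.11; the genome build and the versions of the other tools are not given in the sources used here. The deposited values are counts: per the file headers, each line holds an alignment of 1 distinct read sequence to a miRNA precursor or a tRNA, with the number of reads of that sequence and the mismatches. Alignments carry at most 1 mismatch. Reads aligned to tRNA were 16 to 51 nt long and those aligned to miRNA precursors 16 to 28 nt. A read of 51 nt shows no 3′ end of its fragment.

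Each read was counted 1 time, whatever its number of alignments, so a read sequence entered with its number of reads. tRNA reads were assigned to classes by place, with a tolerance of 3 nt at each end. A tRF-5 starts at the 5′ end of the mature tRNA and has at most 30 nt, and a tiRNA-5 starts there and has at least 31 nt. A tRF-3 and a tiRNA-3 are the equivalents at the 3′ end, an i-tRF touches neither end, and a tRF-1 lies in the trailer after the mature 3′ end. Reads aligned only to a precursor, apart from trailers, formed the pre-tRNA class. The 3′ end was taken as the last CCA spelled by error-free reads, which gave it for 322 of 403 mature tRNA references; reads aligned solely to the others and not at the 5′ end counted as i-tRF, so the 3′ classes miss some reads. A read with alignments in several classes took the class of most of them. A feature is a class and an anticodon, or the set of anticodons that a read matches equally. miRNAs were named by precursor and arm, with the arm set by the middle of the precursor; lengths came from the RefSeq gene table of assembly GRCr8 for 360 of 383 precursors and from the span of the reads for 23. No coordinates were taken from that table. Reads matching several miRNAs were kept as combined features. This gave 536 tsRNA features, 67949 tRNA read sequences and 659 miRNA features.

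Differences were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment, calling adjusted p under 0.05, on all 6 libraries with group as the sole term. CPM values printed are scaled to the reads of the same table without TMM factors, while fold changes include TMM factors. The SE of a log2 fold change was derived from the F statistic. Shares of fragment classes and the log2 ratio of miRNA to tRNA reads were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. Lists of features fixed before the data were examined were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of each table, for lists of at least 3 tested members. The miRNA lists cover the pancreas, neuroendocrine cells, inflammation, stress and hypoxia, and the miR-200, let-7 and miR-30 families. The miR-200 list also holds miR-205. Further lists cover the miR-17-92 clusters and other cell types (stroma and muscle, blood and immune cells, liver). The tsRNA lists cover the fragment classes, mitochondrial tRNA, tiRNA-5 of 6 amino acids often reported under stress, and each amino acid.

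Named features follow a rule written before the data were examined. It takes the called features of largest change, or, where fewer than 10 pass, the 10 with the smallest p at a mean of at least 10 CPM. It adds the 5 most abundant features, the 2 members of each list with the smallest p, tRF-3 Thr-AGT, and the 5 read sequences with the smallest adjusted p in each direction at a mean of at least 10 CPM. Some of these sequences are not reported here.

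The tests were run on simulated counts with the means, library sizes and dispersions of these data, in 5 runs. Among 236 tsRNA features with 40 changed, the edgeR test recovered 57% of 2-fold and 94% of 4-fold changes. Among 341 miRNAs with 40 changed, it recovered 37% and 90%. Among 2233 read sequences with 200 changed, it recovered 2.6% and 31%. For miRNAs, camera called a simulated list of 16 members shifted by 0.40 on the log2 scale in 94% of 50 runs, and 2.8% of unchanged lists had an unadjusted p under 0.05; simulated members vary independently, which real family members need not.

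Alternatives were DESeq2 1.42.0 size factors and its Wald test, other filters, scaling by library totals or over both tables, a replicate block, leaving out each library, error-free reads, reads of 1 anticodon, exact ends, and other read lengths; camera was also run with an estimated correlation and beside fry. Leaving out both libraries numbered 1 and leaving out reads of 51 nt were chosen after seeing the data. Deviations from the group means of same-numbered libraries correlated across miRNAs at 0.28, 0.63 and 0.18 and across read sequences at 0.28, 0.21 and 0.39 for numbers 1, 2 and 3. These are correlations across features, which are not independent. By the rule that every pair exceed 0.1, the numbers were taken to pair the libraries in those tables. In read sequences each untreated library correlated best with its own number. In miRNAs, untreated replicate 1 instead correlated best with taurocholate replicate 3. The labels do not describe a pairing. No pair of libraries agreed within sampling noise: chi-square over degrees of freedom was at least 18.4 for tsRNA features and 49.1 for miRNAs.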

Results

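Small RNA profiles were compared between AR42J cells, a rat pancreatic acinar line, left untreated (3 libraries) or exposed for 30 min to 200 µM sodium taurocholate (3 libraries), a bile salt used to model acute pancreatitis. The question was which tRNA-derived small RNAs (tsRNAs) and miRNAs differ after this exposure. Reads aligned to tRNA numbered 193750, 348451 and 229717 in the untreated libraries and 338310, 254998 and 306389 in the taurocholate libraries. Reads aligned to miRNA precursors numbered 3070227, 3987307 and 2791878, and 3343552, 3780777 and 3637092. tRNA fragments were therefore measured at a lower depth than miRNAs.

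The most abundant class of tRNA fragments was tRF-3, short fragments of the 3′ end, with 46.7% ± 0.943 of tRNA reads in untreated and 47.5% ± 3.10 in taurocholate libraries (SD, n = 3 each). i-tRF, from inside the tRNA, took 20.1% ± 2.12 and 17% ± 2.62. tiRNA-5, long fragments of the 5′ end, took 15.3% ± 4.15 and 16.5% ± 4.12, and tRF-5, the short ones, 11.8% ± 1.19 and 14.1% ± 3.23. Reads aligned only to tRNA precursors took 3.72% ± 0.206 and 3.12% ± 0.417. Trailer fragments, tRF-1, took 1.63% ± 0.109 and 1.12% ± 0.221, and tiRNA-3 0.760% ± 0.160 and 0.640% ± 0.175. In the precursor and tRF-1 classes, both made from tRNA precursors, every taurocholate library lay below every untreated one. Groups that do not overlap, in either direction, came in 2 of 7 classes, and chance gives them in 10% of comparisons. The shares have a common total, so the classes are not independent. The precursor class was apart by little (at the edge, 3.498% untreated and 3.497% with taurocholate), and overlapped with reads of 18 to 40 nt (exact p 0.3) and with each sequence counted 1 time (0.7), as did tRF-1 with the latter (0.4). Their two-sided exact permutation p was 0.1, the smallest this design allows, and 0.35 after Benjamini-Hochberg adjustment over 7 classes. The exact p of the other classes ranged from 0.2 to 0.7. Under other settings, i-tRF were apart with reads of 18 to 40 nt (-4.48 points) and tRF-3 with each sequence counted 1 time (0.887 points). Both had an exact permutation p of 0.1 there and overlapped in the main setting. The share of tiRNA-5 was higher in the taurocholate group by 1.22 percentage points, but lower by 0.924 (exact permutation p 0.1, groups apart) without reads of 51 nt, which were 1.19%, 9.81% and 1.64% of tRNA reads in the untreated and 12.6%, 5.52% and 1.51% in the taurocholate libraries. The log2 ratio of miRNA to tRNA reads was 3.70 ± 0.25 and 3.59 ± 0.29 (SD, n = 3 each), with an exact permutation p of 0.6.

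**Figure D1:**
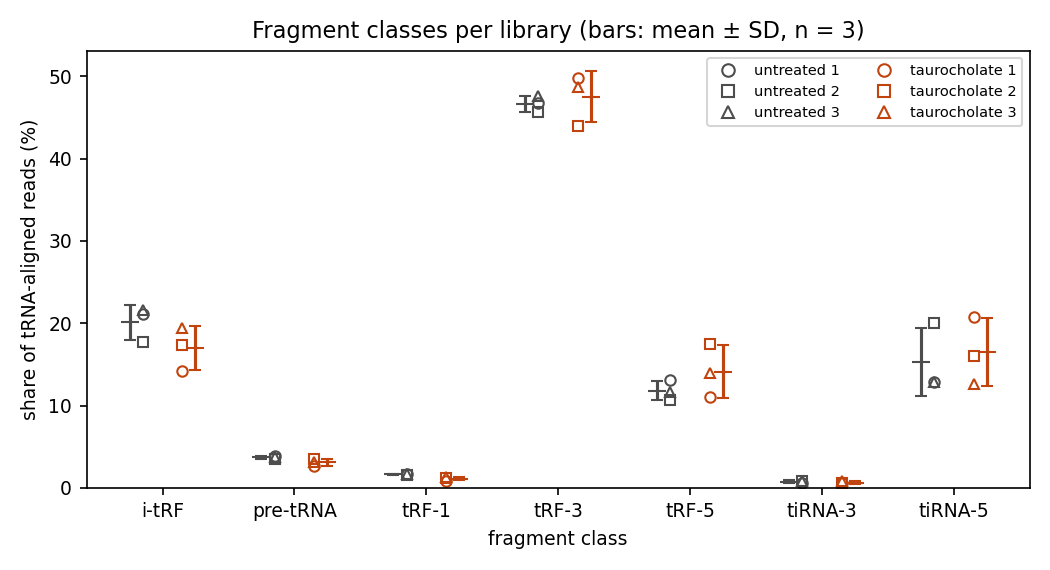
Share of tRNA-aligned reads (%) in each fragment class for the 6 libraries, one marker per library, with the group mean ± SD beside them. The tRF-1 markers of the taurocholate libraries lie below those of the untreated libraries (means 1.12% and 1.63%), while the tRF-3 markers overlap.

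The mean length of reads that start at the tRNA 5′ end, taken between 26 and 40 nt, was 31.6 nt ± 0.0961 in untreated and 31.2 nt ± 0.189 in taurocholate libraries (SD, n = 3 each), a difference of -0.412 nt. Every taurocholate library lay below every untreated one, with a two-sided exact permutation p of 0.1. The measure was chosen after the data were seen, as 1 of 14 compared without a plan. Of these, 5 separated the groups, where chance gives 10% for a single measure, and the 14 are not independent.

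**Figure D2:**
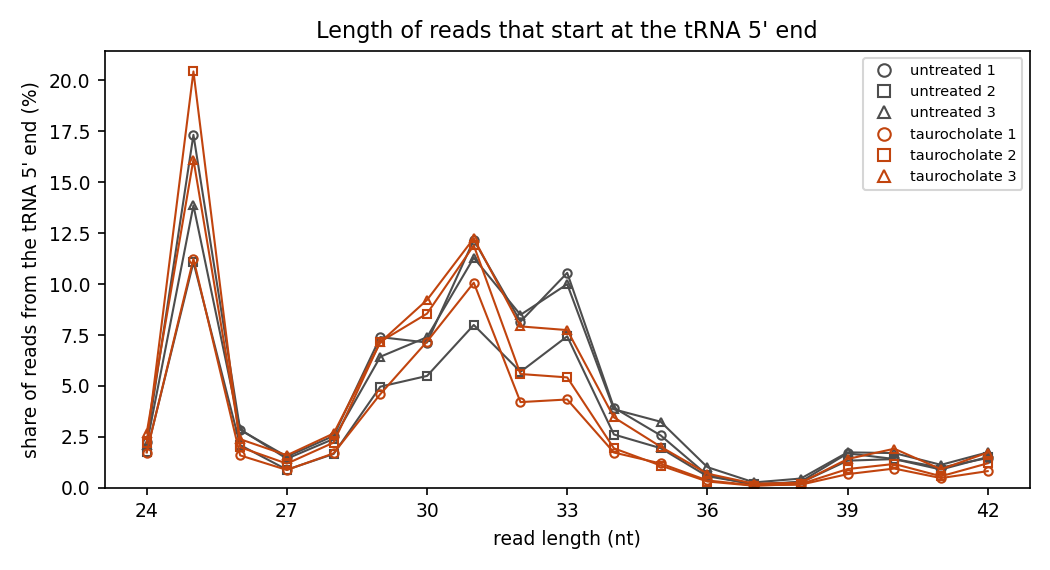
Length (nt) of reads that start at the tRNA 5′ end, as the share (%) of all such reads, with a line per library. At 33 nt the untreated libraries hold 7.44% to 10.6% and the taurocholate libraries 4.34% to 7.74%.

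Of 236 tsRNA features tested, none passed an adjusted p of 0.05 in the edgeR quasi-likelihood test. At an unadjusted p under 0.05 there were 24, of which 13 were higher with taurocholate, and the smallest adjusted p was 0.384. The DESeq2 Wald test also called 0, with 21 at an unadjusted p under 0.05, of which 12 were higher; 7 of 21 were higher with TMM over both tables. The following values are of the features with the smallest p, none past the threshold. tRF-1 His-GTG was at 1283 ± 87.7 CPM untreated and 656 ± 148.5 CPM with taurocholate (SD, n = 3 each), a log2 fold change of -0.84 (SE 0.19). tRF-5 Leu-CAG was at 6399 ± 666 and 9106 ± 825 CPM, a log2 fold change of 0.64 (SE 0.16). tRF-5 Gly-CCC/GCC was at 8989 ± 1514 and 13366 ± 1733 CPM, a log2 fold change of 0.73 (SE 0.19). Log2 fold changes were also positive for tRF-5 Ile-AAT (0.73), tRF-5 Gly-CCC (0.62) and tRF-3 Leu-TAG (0.55). They were negative for the precursor fragments of Glu-CTC (-0.90), Pro-CGG (-0.76) and Leu-TAG (-0.53) and for tRF-1 Met-CAT (-0.58).

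The most abundant tsRNA was tRF-3 Tyr-GTA, at 105347 ± 15260 CPM untreated and 102029 ± 4527 CPM with taurocholate (SD, n = 3 each). Its log2 fold change was 0.09 (SE 0.17), and -0.05 with library totals. The next were tRF-3 Ala-CGC/TGC (log2 fold change 0.36, SE 0.16; 0.16 without taurocholate replicate 1), tRF-3 Cys-GCA (-0.11, SE 0.14, and -0.18 to -0.04 leaving out 1 library), tiRNA-5 Lys-CTT (0.35, SE 0.32, 0.03 without reads of 51 nt, and -0.01 to 0.72 leaving out 1 library) and tRF-3 Leu-AAG/TAG (0.23, SE 0.14, and 0.11 without taurocholate replicate 1). tRF-3 Thr-AGT, a fragment known from work on acute pancreatitis, was at 5834 ± 646 and 5394 ± 920 CPM. Its log2 fold change was 0.03, with an interval of 2 SE from -0.30 to 0.35, and the edgeR quasi-likelihood adjusted p was 0.956. It was -0.06 with error-free reads, -0.02 with TMM over both tables and -0.11 with library totals.

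Among the fixed lists of fragment classes, tRF-3 and tRF-5 stood higher with taurocholate against the other features with a preset correlation, but with an estimated correlation both had an adjusted p = 0.728. Of 51 tRF-3 features 38 were higher, with a median log2 fold change of 0.13 and a camera adjusted p of 0.0131. Of 34 tRF-5 features 26 were higher, with a median of 0.15 and a camera adjusted p of 0.0236. No member of either list was called, also when adjusted over the list alone. The tRF-3 call was lost without untreated replicate 1 (adjusted p 0.0961), without taurocholate replicate 1 (0.688) and with error-free reads (0.0883). The tRF-5 call was lost without untreated replicate 2 (0.111), taurocholate replicate 2 (0.0530) or taurocholate replicate 3 (0.154). With library totals in place of TMM the median of all tsRNA features moved from 0.01 to -0.12, with 3 of 21 features at an unadjusted p under 0.05 higher. The list medians moved with it, to -0.003 for tRF-3 and 0.01 for tRF-5. Such a change of scaling moves all features nearly alike, so it does not test the lists against the other features. With a replicate block the tRF-5 adjusted p was 0.0570. Taurocholate replicate 1 carried a mismatched G as last base in 20.96% of its tRNA reads and untreated replicate 1 in 7.26%, against 1.28% to 1.93% in the other 4 libraries.

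The other class lists did not pass. i-tRF were lower in 39 of 57 features (median -0.11, camera adjusted p 0.114), with i-tRF Ile-TAT at -0.74 and i-tRF Gly-CCC at -0.91 (-0.29 without untreated replicate 3). tiRNA-5 were higher in 14 of 24 (median 0.26, adjusted p 0.924; median -0.28, adjusted p 0.126 without reads of 51 nt), with tiRNA-5 Pro-CGG at -0.96 (-0.56 without untreated replicate 2) and tiRNA-5 Cys-GCA at -0.52. The tiRNA-5 of Gly, Glu, Val, His, Asp and Lys were higher in 11 of 14 (median 0.34, adjusted p 0.377; median 0.004, adjusted p 0.697 without reads of 51 nt), with tiRNA-5 Gly-CCC/GCC at 0.41 and tiRNA-5 Glu-TTC at -0.30. tiRNA-3 were higher in 5 of 14 (median -0.07, adjusted p 0.805), with tiRNA-3 mt-Leu-TAA at 0.58 (0.91 without untreated replicate 2) and tiRNA-3 Asn-GTT at -0.47 (-0.22 without untreated replicate 3, -0.27 without taurocholate replicate 2). tRF-1 were higher in 6 of 11 (median 0.06, mean -0.10, adjusted p 0.547 with a lower direction), and tRF-1 His-GTG was called when adjusted over the list alone. Mitochondrial tRNA fragments were higher in 4 of 6 (median 0.18, adjusted p 0.599), with i-tRF mt-Gln-TTG at -0.43 (-0.18 without untreated replicate 3, -0.20 and -0.71 without taurocholate replicates 1 and 2).

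No list of a single amino acid passed, with camera adjusted p from 0.126 to 0.816. The smallest were Pro, lower in 14 of 16 features (median -0.23, adjusted p 0.126), and Val, higher in 16 of 21 (median 0.24, adjusted p 0.126), with tRF-3 Val-TAC at 0.40 and tRF-5 Val-CAC at 0.52. Gly was higher in 15 of 21 (median 0.28, adjusted p 0.286, and a median of 0.06 without reads of 51 nt), with tRF-3 Gly-TCC at 0.44. The adjusted p was 0.462 for Ala and His, 0.547 for Glu, Ser, Trp and Tyr, 0.551 for Leu, 0.599 for Arg, Asn, Cys, Gln and Met, 0.602 for Asp and Lys, 0.617 for Phe and 0.805 for Ile. Adjusted over the list alone, tRF-1 His-GTG was called in the His list and tRF-5 Ile-AAT in the Ile list. The 12 features of Thr had a median of 0.01 and an adjusted p of 0.816, with i-tRF Thr-CGT at -0.43 (-0.67 and -0.10 without untreated replicates 2 and 3) and tRF-1 Thr-TGT at 0.27 (-0.18 without taurocholate replicate 2, 0.15 to 0.50 without another). SeC had 2 features and was not tested as a list; tiRNA-5 SeC-TCA was at -0.91 (-0.60 without untreated replicate 2) and i-tRF SeC-TCA at -0.22 (-0.46 to 0.20 leaving out 1 library).

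Among 2233 tRNA read sequences tested singly, none was called by the edgeR quasi-likelihood test (smallest adjusted p 0.302), 315 had an unadjusted p under 0.05 and 156 of these were higher, against 36 of 168 with library totals. The DESeq2 Wald test also called 0. The higher sequences of smallest p included the 22-nt 5′ fragment TTCGATAGCTCAGCTGGTAGAG of Tyr-GTA (1.61), the 21-nt 3′ fragment CGATCCCCGGCATCTCCACCA of Ala-CGC/TGC (1.38) and the 30-nt 5′ fragment GCATTGGTGGTTCAGTGGTAGAATTCTCGA of Gly-CCC/GCC (1.51), which carries 1 mismatch. The lower ones were the internal 36-nt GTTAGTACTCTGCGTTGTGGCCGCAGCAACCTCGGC of His-GTG (-2.47, SE 0.37) and 5′ fragments of Val-CAC (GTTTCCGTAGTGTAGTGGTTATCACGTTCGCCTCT, -1.47), His-GTG (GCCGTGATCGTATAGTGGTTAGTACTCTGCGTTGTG, -1.79), Glu-TTC (TCCCACATGGTCTAGCGGTTAGGATTCCC, -1.08) and Gly-CCC/GCC (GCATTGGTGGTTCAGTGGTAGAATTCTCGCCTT, -1.22). Of the lower ones, those of Val-CAC, Glu-TTC and Gly-CCC/GCC and the internal one of His-GTG also carry 1 mismatch. Longer reads of the same tRNAs place each mismatch at the last base. It is a C in the internal one of His-GTG and in Glu-TTC. A mismatched last C was less frequent in the tRNA reads of every taurocholate library (1.65%, 2.84% and 3.13%) than in untreated ones (3.52%, 3.45% and 3.40%). For the last T of the other 2 the groups overlapped. Whether this accounts for their change was not tested. None of these 8 passed the adjusted threshold, and some rested on few reads. The internal one of His-GTG had 11, 15 and 13 reads untreated and 2, 2 and 3 with taurocholate. That of Tyr-GTA had 4, 9 and 8 untreated and 23, 20 and 22 with taurocholate. That of Ala-CGC/TGC had 5, 11 and 6 untreated and 15, 19 and 25 with taurocholate.

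Of 341 miRNAs tested, none passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, and the smallest adjusted p was 0.135. At an unadjusted p under 0.05 there were 57, of which 20 were higher. The DESeq2 Wald test called 0, with 46 at an unadjusted p under 0.05, of which 29 were higher. With other scaling 14 of 25 (library totals) and 30 of 61 (TMM over both tables) were higher, so the direction depends on the scaling. The library was led by miR-148a-3p, a miRNA abundant in pancreas, at 381030 ± 36243 CPM untreated and 335922 ± 63270 CPM with taurocholate (SD, n = 3 each; log2 fold change -0.20, SE 0.27, and -0.52 to 0.02 leaving out 1 library). miR-21-5p, tied to inflammation, was at 203323 ± 8540 and 259459 ± 7531 CPM (0.30, SE 0.13). The next most abundant were miR-7a-5p (-0.32, SE 0.08), let-7i-5p (-0.22, SE 0.12, and -0.09 and -0.13 without untreated replicate 1 and taurocholate replicate 3) and let-7f-5p (-0.33, SE 0.09). Among those of smallest p, miR-25-3p was at 2194 ± 205.6 and 2988 ± 419 CPM (0.38, SE 0.09), miR-99b-5p at 6020 ± 683 and 8501 ± 1397 CPM (0.44, SE 0.11) and miR-22-3p at 3608 ± 252 and 2950 ± 459 CPM (-0.36, SE 0.09). miR-196b-5p had a log2 fold change of 0.46 (SE 0.12) and the reads shared by miR-196a and miR-196c, 5p arm, -0.78 (SE 0.20).

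The let-7 family, regulators of growth and differentiation, was lower as a list: 13 of its 16 tested members were lower, with a median log2 fold change of -0.34 and a camera adjusted p of 0.00185. With an estimated correlation the let-7 adjusted p = 0.156, so the call was lost. No member was called over all miRNAs; adjusted over the list alone, 7 were: the 5p arms of let-7a, let-7b, let-7c, let-7d, let-7e and let-7f, and miR-98-5p. let-7e-5p was at 1589 ± 208 CPM untreated and 1179 ± 220 CPM with taurocholate (SD, n = 3 each), a log2 fold change of -0.50 (SE 0.11). let-7c-5p had -0.57 (SE 0.13) and let-7a-5p -0.49 (SE 0.11). let-7g-5p, outside the list as fixed, had -0.35 (SE 0.08). On library totals the median level of the members, on the log2 scale about their means, was 0.01, 0.13 and 0.29 in the untreated and 0.03, -0.50 and 0.03 in the taurocholate libraries. Its group difference of -0.29 was -0.11 without taurocholate replicate 2, so on this scale much of it came from this library. The scale leaves out the TMM factors, which the median of -0.34 and the list call include. These were 0.833 for taurocholate replicate 2 and 1.16 for taurocholate replicate 1, so the reading may not hold on the scale of the call. The list was also lower with library totals (median -0.29, adjusted p 0.0114) and with error-free reads (adjusted p 0.000274).

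**Figure D3:**
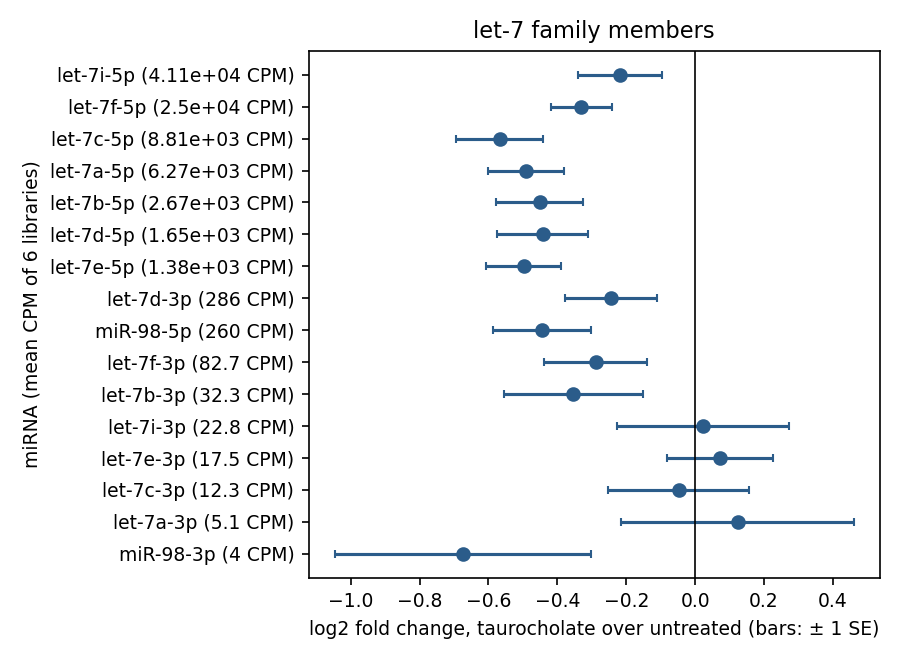
Log2 fold change of each let-7 family member, taurocholate over untreated, with bars of 1 SE, ordered by mean CPM of the 6 libraries. Of the 16 members 13 lie left of 0, and the median is -0.34.

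The 6 members of the epithelial miR-200 list were all higher, with a median log2 fold change of 1.06. They include both arms of miR-200a, and miR-205-5p, which is not of the miR-200 family. The camera adjusted p of the list was 0.0713, which missed the threshold. With a replicate block it was 0.00689 and the list was called. With an estimated correlation the adjusted p = 0.715. miR-141-3p had a log2 fold change of 1.74 (SE 0.85) and miR-200a-5p 1.499 (SE 1.09), both at a mean under 10 CPM; without untreated replicate 1 they had 3.39 and 3.72. The groups overlapped in level: miR-200b-3p was at 200.3, 21.3 and 43.7 CPM in the untreated and 209, 24.9 and 260.4 CPM in the taurocholate libraries. Within all 3 same-numbered pairs 5 of the 6 members were higher with taurocholate. The exception, miR-205-5p, was higher in 2 of 3 pairs. Chance gives 1 sign in all pairs to 25% of miRNAs, and family members are not independent. The labels do not describe this pairing, on which the replicate block also rests. Across miRNAs untreated replicate 1 correlated best with taurocholate replicate 3. Leaving out a library that went against the difference lowered the camera adjusted p. It was 0.000164 without untreated replicate 1, the untreated library highest in miR-200b-3p. It was 0.00305 without taurocholate replicate 2, the taurocholate library lowest in it. With library totals the adjusted p was 0.0372. The epithelial miR-194-5p, outside the list, went with it (322, 108.8 and 135.8 CPM untreated; 492, 105 and 582 CPM with taurocholate), as did miR-192-5p and miR-215-5p, high in the same 3 libraries, untreated replicate 1 and taurocholate replicates 1 and 3. miRNAs of other tissues also varied between libraries within both groups, such as the muscle miRNA miR-1b-3p at 1266, 9.53 and 38.7 CPM in the untreated and 104.7, 80.1 and 574 CPM in the taurocholate libraries.

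**Figure D4:**
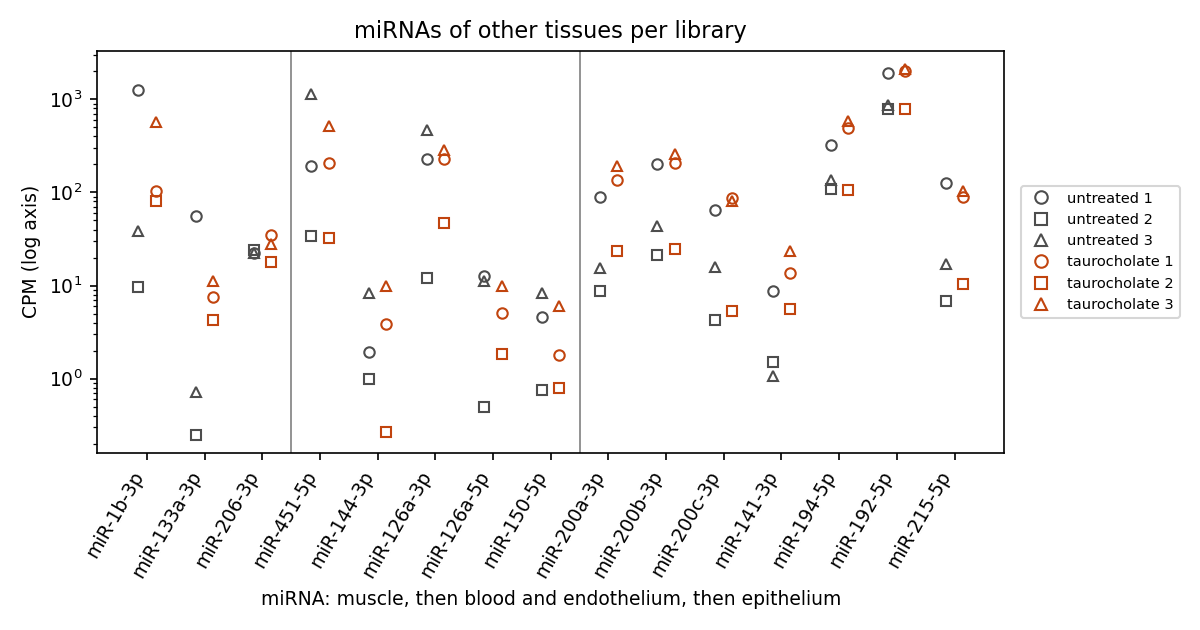
CPM (log axis) of miRNAs known from muscle, from blood and endothelium, and from epithelium in the 6 libraries, one marker per library. Levels of single miRNAs such as miR-1b-3p range from 9.53 to 1266 CPM, and high and low libraries occur in both groups.

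The remaining miRNA lists did not pass. Stress and hypoxia miRNAs were higher in 11 of 15 (median 0.21, camera adjusted p 0.269), with miR-22-3p at -0.36 and miR-24-3p at 0.28. Inflammation miRNAs were higher in 9 of 18 (median 0.01, adjusted p 0.615), with miR-146b-5p at -0.42 (-0.19 without untreated replicate 2). Pancreas miRNAs were higher in 2 of 6 (median -0.18, mean 0.03, adjusted p 0.582); miR-7a-5p and miR-7b-5p (-0.51) were called when adjusted over the list alone. Neuroendocrine miRNAs were higher in 4 of 10 (median -0.18, adjusted p 0.843), with 3 called when adjusted over the list alone, miR-7a-5p, miR-7b-5p and miR-9a-5p. The miR-17-92 clusters were higher in 8 of 14 (median 0.07, mean -0.02, adjusted p 0.582), with miR-19a-3p at -0.48 (-0.28 without untreated replicate 2). The miR-30 family was lower in 8 of 10 (median -0.10, adjusted p 0.582), with miR-30e-5p at -0.48 and miR-30a-5p at -0.30 (-0.18 without untreated replicate 2). Among lists of other cell types, stromal and muscle miRNAs were lower in 10 of 14 (median -0.11, adjusted p 0.582), with miR-199a-3p at -0.37 (-0.24 without taurocholate replicate 2) and miR-145-3p at -0.26 (-0.17 without untreated replicate 1). Blood and immune miRNAs were lower in 5 of 9, with a median of -0.20 although the test pointed up (adjusted p 0.588), with miR-142-3p at 0.41 and miR-486-3p at 0.29 (0.15 without untreated replicate 3, 0.18 without taurocholate replicate 1). miR-122-5p, the sole liver miRNA of the lists, was at -0.47 (SE 0.39), at -0.12 without taurocholate replicate 2 and at -0.17 without untreated replicate 1.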

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

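All tests in this part were chosen after the values were seen. Values are given where a treated library lay above the highest untreated library, or all lay below the lowest, in a read property outside the comparisons. A mismatched G as last base was found in 21% of tRNA reads and 22.1% of miRNA reads of taurocholate replicate 1, against at most 7.26% and 5.32% in an untreated library. A mismatched last A was found in 8.60%, 10.6% and 11.3% of miRNA reads in taurocholate replicates 1, 2 and 3, against at most 8.39% untreated, and in 5.77% and 5.84% of tRNA reads in taurocholate replicates 2 and 3, against at most 5.49%. A mismatched last T was found in 7.90% and 8.73% of miRNA reads of taurocholate replicates 2 and 3, against at most 7.06%. A mismatched last C went the other way: it was found in 9.30%, 11.2% and 10.2% of miRNA reads in the untreated and 5.08%, 8.03% and 7.79% in the taurocholate libraries, and in 3.52%, 3.45% and 3.40%, and 1.65%, 2.84% and 3.13% of tRNA reads, with an exact permutation p of 0.1 for each. Reads of 51 nt made up 12.6% of tRNA reads in taurocholate replicate 1, against at most 9.81%. Such read properties and the mean lengths of fragment classes made 14 measures compared without a plan. In 5 of them the groups did not overlap, where chance gives 10% for a single measure. The measures come from the same reads and are not independent, so this does not show an excess.

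miRNAs of other tissues varied between libraries within both groups. miR-1b-3p, a muscle miRNA, was at 1266, 9.53 and 38.7 CPM in the untreated and 104.7, 80.1 and 574 CPM in the taurocholate libraries, and miR-451-5p, of red blood cells, at 191, 34.4 and 1148, and 209, 32.5 and 516 CPM. A lower share of AR42J cells, with other RNA in a constant mix, would raise muscle and blood sets alike. Yet the difference of their set medians ranged over 5.45 on the log2 scale across libraries. The SD of members about their set medians was 0.69. A lower share with a varying mix was not tested. In the muscle set miR-206-3p did not vary with the other 2 members. RNA of several tissues carried into the libraries may account for it: the range of each set between libraries was at least 4.79 times the SD of its members. These sets were assembled after the levels of several members had been seen, so that value leaves it open, and no biological explanation was tested. Of the 7 epithelial members 4 also belong to the miR-200 list.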

How the results depend on the processing

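The alternatives without both libraries numbered 1, without reads of 51 nt, and for the fixed lists error-free reads and library totals, were chosen after seeing the data. The count of 0 called miRNAs held under all 16 alternatives. For tsRNA features it held under 17 of 19; exact ends called 1 (tiRNA-5 Cys-GCA) and no filter on low counts called 3. For read sequences it held under 16 of 17; no filter called 125, of which 88.8% end in G, against 20.3% of all sequences. With a replicate block 0 features, 0 miRNAs and 0 sequences were called; the block changed no other call than the lists given here. In tsRNA features same-numbered libraries correlated at -0.20, 0.04 and 0.29, so the numbers do not pair that table.

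The let-7 list (adjusted p 0.00185) had 0.156 with an estimated correlation. Its adjusted p leaving out 1 library and its fry result are not reported here. The count of miRNA lists called, given below, does not show whether let-7 kept its call. The tRF-5 list had 0.728 with an estimated correlation, 0.0570 with a replicate block and 0.000239 to 0.154 leaving out 1 library. The tRF-3 list had 0.728 with an estimated correlation, 0.894 without both libraries numbered 1, 0.0883 with error-free reads and 8.37e-06 to 0.688 leaving out 1 library. The number of tsRNA lists called, 2, was 0 with an estimated correlation, 1 with a replicate block, 1 without both libraries numbered 1 and 1 to 3 leaving out 1 library. The number of miRNA lists called, 1, was 0 with an estimated correlation, 2 with a replicate block, 2 without both libraries numbered 1, 2 with library totals and 1 to 2 leaving out 1 library. fry asks another question, whether the members of a list move on balance in one direction, and does not compare them with other features. It gave an adjusted p of 0.476 for both the tRF-5 and the tRF-3 list and called 0 tsRNA lists. The cause was not tested.

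Differences that changed sign were these: the log2 ratio of miRNA to tRNA reads (-0.11) was 0.13 with each sequence counted 1 time and -0.265 to 0.0283 leaving out 1 library. The share of tRF-3 (0.849 points) was -0.313 with error-free reads and -0.326 to 2.60 leaving out 1 library. The share of tiRNA-5 (1.22 points) was -1.90 with reads of 18 to 40 nt, -0.924 without reads of 51 nt and -0.951 to 3.61 leaving out 1 library; the first 2 of these had an exact permutation p of 0.1, so every taurocholate library lay below every untreated one. The log2 fold change of tRF-3 Thr-AGT (0.03) was -0.0198 with TMM over both tables, -0.113 with library totals and -0.0595 with error-free reads. That of tRF-3 Tyr-GTA was -0.0462 with library totals. Without both libraries numbered 1, that of pre-tRNA Asp-GTC was -0.0171, of tRF-3 Phe-GAA -0.0126, of tiRNA-5 Lys-CTT -0.0923 and of miR-148a-3p 0.210. That of pre-tRNA Met-CAT was 0.0764 with error-free reads. Leaving out 1 library, the values ran from -0.458 to 0.199 for i-tRF SeC-TCA, -0.184 to 0.502 for tRF-1 Thr-TGT, -0.0148 to 0.392 for tRF-3 Phe-GAA, -0.0325 to 0.0829 for tRF-3 Thr-AGT, -0.0107 to 0.214 for tRF-3 Tyr-GTA, -0.00625 to 0.717 for tiRNA-5 Lys-CTT and -0.517 to 0.0161 for miR-148a-3p. Over all named features, 1508 alternative values kept direction and side of the threshold, 17 changed sign and 2 brought a call, that of tiRNA-5 Cys-GCA with exact ends and that of 1 sequence without a filter. The cause was not tested.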

Other observations

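The test of GC content was set before its result was seen; the other tests in this part were chosen after. The let-7 list was lower with taurocholate with a preset correlation, and the call is lost with an estimated correlation (adjusted p 0.156). The libraries numbered 1, which carry more reads with a mismatched last G, do not account for it, since the camera adjusted p was 0.00709 without both. Reads that match several let-7 paralogs equally formed combined features outside the list, so they were not part of the call. Error-free reads therefore test only reads placed on a paralog with a mismatch. These do not account for the call, since the adjusted p was 0.000274 without them. For GC content, the median of -0.34 lay at the 0.05 percentile of 10000 random miRNA lists matched on GC. GC was known for 16 of 16 members. The random lists were drawn as single miRNAs, while family members need not vary independently. The percentile may thus be too extreme, and it does not by itself exclude GC content. In level on library totals the group difference went from -0.29 to -0.11 without taurocholate replicate 2. That scale leaves out the TMM factors that the list call includes. A difference in read properties between the groups stays open, since the shares of a mismatched last C and last A in miRNA reads also separate them. Base qualities were not examined, and of these shares only last C was set against let-7. Within the groups the slope of the let-7 level on library totals was -0.0631 per percentage point of mismatched last C. Its 95% interval from -0.372 to 0.245 holds both 0 and the slope between the groups, 0.0874. A response to taurocholate could not be told from such a difference.

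Reads from the tRNA 5′ end were shorter with taurocholate by a mean difference of -0.412 nt, between -0.516 and -0.332 nt when 1 library was left out. Mismatched bases at the read end do not account for it, since the difference was -0.378 nt with error-free reads. Among the 20 most read anticodons, or sets of anticodons that a read matches equally, 19 had shorter fragments, 10 of them with groups apart. Another mix of these sets therefore does not account for the difference alone. Where a read ends can decide which set it matches, so the sets are not single tRNAs. The untreated mean was 30.8 nt for Gly-CCC/GCC and 33.8 nt for Gly-GCC. Another mix of tRNAs within a set stays open. Size selection of the libraries could account for the shorter reads and stays open: the difference was 0.0203 nt for tRF-1, 0.258 nt for tiRNA-3, -0.555 nt for i-tRF and -0.232 nt for pre-tRNA. Cleavage nearer the 5′ end after taurocholate was not tested.

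With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 0 tsRNA features, 0 miRNAs, 0 read sequences, 2 tsRNA lists and 1 miRNA list. The highest other splits called 5, 10, 61, 5 and 1. For the features, with a real count of 0, all 10 splits give as many by construction, so that number shows nothing; 7 did for tsRNA lists and 5 for miRNA lists. By the rule of correlations above 0.1 the numbers pair the libraries in the miRNA and sequence tables. The labels give no pairing, and in miRNAs untreated replicate 1 correlated best with taurocholate replicate 3. If the pairing is taken as given, 4 splits, the real one included, part all 3 pairs. Among these the other 3 called 0 miRNAs, 0 sequences and 0 miRNA lists, and 4 are again too few for a share under 0.05. The calls of miRNAs and sequences in other splits came where a pair was joined on one side, and these splits, with more calls than the real one, point to a structure of the samples. The split with 5 tsRNA features and that with 61 sequences both put untreated replicates 1 and 3 with taurocholate replicate 3, the 3 libraries with the lowest shares of 51-nt reads (1.19%, 1.64% and 1.51%), and the 5 features were tiRNA-5 of Gly and Val. The split with 10 miRNAs put untreated replicate 1 with taurocholate replicates 1 and 3, and its miRNAs were those of the miR-200, miR-192, miR-194 and miR-215 families and miR-375, known from epithelia and endocrine cells.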
